A study of Mus musculus with 6 samples.

How the data were processed

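Gene expression was measured in whole mouse lung after 7 days of hypoxia, on 6 single-colour Affymetrix arrays hybridised with biotin-labelled cRNA. The groups held 3 control arrays and 3 arrays from mice lacking Nfat5 in endothelial cells (EC knockout). Per the labels' protocols, gene ablation was induced in adult mice of both sexes, aged 10 to 12 weeks, by intraperitoneal tamoxifen at 1 mg per day on 5 days, and controls carried the floxed alleles and received the oil solvent. The knockout mice therefore differed from the controls in genotype and in tamoxifen together. A recovery of 2 to 3 weeks followed, and lungs were perfused with cold Ringer solution before lysis. The series design states 4 mice per group and says that preparations with contaminating tissue, thymus for example, or with inadequate expression responses to hypoxia were left out by the authors, so the arrays were in part selected on expression. The sex of each animal is not given in the sources used here.

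The deposited values are log2 expression per probe set, summarised with RMA per the submitters' processing notes; the RMA version and the probe set definition are not given in the sources used here. From the values, the authors' table was normalized to common quantiles: 5 columns held identical quantiles and control replicate 1 differed from them by at most 0.00183, with 24668 distinct values against 10964 in each other column. Every array had a median of 2.98 and a maximum of 13.0 on the log2 scale. The table carried no detection calls, so dim probe sets could not be told from absent transcripts, and the number of arrays limits the precision.

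Of 25428 probe sets, 24705 had 1 gene symbol in the platform annotation, 0 had several and 723 were unnamed here. Entrez identifiers matched the RefSeq gene table of assembly GRCm38.p6 for 24673 probe sets, which supplied biotype and gene length (the span of the gene) and changed 0 symbols. For the 1 symbol with 2 probe sets the brighter was kept, which left 24704 genes. No filter on dim genes was applied.

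Knockout and control arrays were compared per gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values), with Benjamini-Hochberg adjustment over all 24704 genes and a threshold of 0.05. Errors of log2 fold changes are limma's moderated standard errors. Gene lists written before the data were examined were tested with camera, using a preset inter-gene correlation of 0.01, with adjustment over 44 lists of at least 4 measured genes. Camera with an estimated correlation, rank-based camera and fry were run as alternatives. Lists of markers for other cell types and tissues were among the 44.

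Genes were named by a rule fixed before the data were examined: Nfat5; the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, leaving out predicted genes, microRNAs, snoRNAs, scaRNAs, snRNAs, receptor and immunoglobulin segments and chemoreceptors; up to 4 members of smallest p in each list described; and the sex-linked genes per array. Genes named outside this rule are marked as such. RNA classes, gene families and gene length were examined after the calls had been seen.

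The procedure was tested on simulated data for the same comparison and 24704 genes, with the means and residual spread of the real arrays. It recovered 0 of 67 genes changed by 0.5 log2 units, 6 of 67 changed by 1 and 36 of 66 changed by 2, with 0 in the wrong direction and 0 unchanged genes called. The simulation called 45 genes in all, against 6292 in the real comparison. Its adjusted threshold was therefore stricter, and these recovered shares do not carry over to the real data. Noise was drawn separately for each gene, so shifts shared by the genes of an array were not simulated.

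Alternatives set before the data were examined covered filters on mean level, averaging of probe sets, inclusion of unnamed probe sets, renewed scaling, limma's intensity trend, array weights, a replicate block, Xist as a covariate, other thresholds, and leaving out each array. Added after seeing the data were a restriction to protein-coding genes, removal of the trend with gene length from each array (lowess, span 0.3), and the median snoRNA level as a covariate.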

Results

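The series asked how loss of the osmosensitive transcription factor NFAT5 from endothelial cells changes the lung's gene expression during hypoxia. Whole-lung RNA from 3 control and 3 EC knockout mice, all kept in hypoxia for 7 days, was profiled on arrays that measured 24704 named genes. Arrays of the control group correlated with each other at 0.968 to 0.970 across genes. The knockout arrays correlated with each other at 0.916 to 0.939 and with the controls at 0.829 to 0.919, where genes are not independent replicates. The first principal component held 62.4% of the variance and separated the groups, with controls between −62.8 and −44.7 and knockouts between 35.7 and 70.5.

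Nfat5 itself (Entrez gene 54446) was lower in the knockout lungs. Its log2 value was 6.51 ± 0.18 in controls and 4.28 ± 0.34 in knockouts (SD, n = 3 each), a 4.69-fold fall. The log2 fold change was −2.23 ± 0.23 (SE; limma, adjusted p = 0.0015), and all 3 knockout arrays (3.89 to 4.48) lay below all 3 control arrays (6.30 to 6.65). Fold changes as low or lower were found for 66 genes, Nfat5 included, or 0.267% of those tested. The labels do not say which part of the gene was deleted or where the probes lie, so the value checks the labels only if the probes cover the deleted part.

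The knockout differed from the control across a broad share of the genes measured: 6292 genes (25.5%) passed the threshold, 3083 higher and 3209 lower. Of these, 3810 changed more than 2-fold, 1685 upward and 2125 downward. The groups did not overlap at 10352 genes (41.9%), where chance gives 10%. The count depended on single arrays, though no call changed sign when 1 array was left out. It fell to 2882 without control replicate 3, to 3141 without control replicate 1 and to 4457 without control replicate 4. Without 1 knockout array it was 5686 to 6155. It was 2827 with Xist as a covariate. Xist was high on control replicate 1 alone (8.22, against 2.03 to 2.37 on each other array), so this setting nearly repeats leaving that array out. With the median snoRNA level as a covariate, which separates the groups without overlap, 0 genes passed (3576 genes at an unadjusted p under 0.05).

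Among genes kept by the naming rule, which left out snoRNAs and scaRNAs, histone genes and the RNA parts of ribonucleoproteins dominated the largest rises. Most of these histone genes were replication-dependent, the kind that packages newly made DNA. H2ac4 rose by 3.22 ± 0.33 log2 units, H4c3 by 3.08 ± 0.31, H1f2 by 2.88 ± 0.28, H2bc15 by 2.77 ± 0.33 and H2ac20 by 2.76 ± 0.28 (SE, n = 3 per group). H4f16, a histone gene not counted in the replication-dependent class below, rose by 2.75 ± 0.25. Rpph1, the RNA of RNase P, rose by 2.73 ± 0.27 and the related Rprl2 by 2.88 ± 0.44. Obox3, a homeobox gene of the early embryo, rose by 3.28 ± 0.55 from a control level of 1.32, below the arrays' lower quartile of 2.02, and Carnmt1, a carnosine methyltransferase, by 2.86 ± 0.33. The adjusted p of these 10 genes lay between 0.0011 and 0.0044.

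The largest falls came from genes of varied function. Pcdhga6, a gamma protocadherin, had a log2 fold change of −3.18 ± 0.25, Uprt −2.89 ± 0.48, Rnf141 −2.87 ± 0.27 and Phxr4 −2.73 ± 0.23. Tgs1, which modifies the caps of small RNAs, stood at −2.71 ± 0.36, complement component Hc at −2.69 ± 0.55 and Cldn34c2 at −2.67 ± 0.28. Pde7b, a cyclic AMP phosphodiesterase, stood at −2.59 ± 0.18, Nbeal1 at −2.50 ± 0.30 and Ppp4r2 at −2.49 ± 0.32 (SE, n = 3 per group). The knockout means of Pcdhga6 (1.44) and Cldn34c2 (1.55) lay below the lower quartile of 2.02, where background is not known, so the sizes and ranks of their falls are uncertain, as is that of the rise of Obox3. The adjusted p of the 10 falls lay between 0.0011 and 0.0087, and Hc did not pass with Xist as a covariate (−2.50, adjusted p = 0.052).

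**Figure D1:**
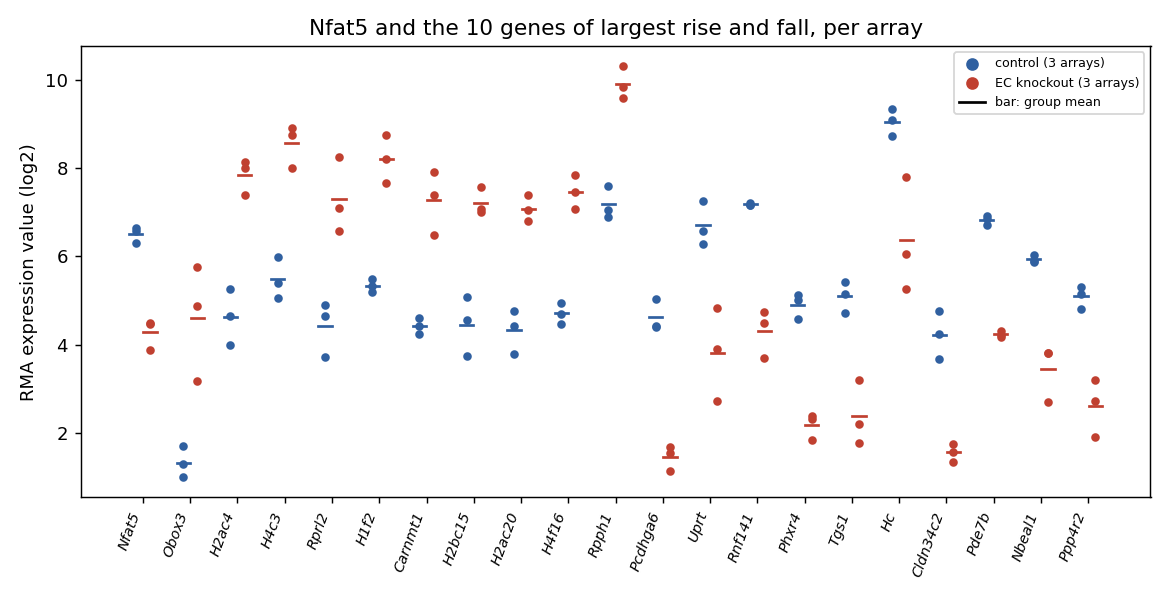
Log2 RMA values per array for Nfat5 and the 10 genes of largest rise and largest fall (points, 3 arrays per group; bars, group means). The rises and falls were chosen among genes whose control and knockout arrays do not overlap. Nfat5, named beforehand, lies at 6.30 to 6.65 in controls and 3.89 to 4.48 in knockouts.

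Genes were also counted by RNA class, with no test of a class as a set. Of 106 snoRNAs, the small RNAs that guide modification of ribosomal RNA, 80 were higher and 0 lower, with a median log2 fold change of 2.10. The median snoRNA level per array was 4.01 to 4.20 in controls and 6.43 to 7.43 in knockouts. Of 8 scaRNAs 5 were higher and 0 lower, and all 6 RNAs of RNase P, RNase MRP, telomerase and the Y RNA were higher, by a median of 1.82. Replication-dependent histone genes were higher at 22 of 45 and lower at 0, with a median of 0.69. That median depended on dim members, at 1.94 over the 28 histone genes above the 25th percentile of mean level and 2.49 over the 21 above the median. Of 534 microRNA genes 43 were higher and 40 lower. Their median level per array was 1.81 to 2.05, near the arrays' lower quartile of 2.02, so changes in them may have been missed. Of 199 immunoglobulin V segments 6 were higher and 25 lower, and of 377 Zfp genes 34 were higher and 74 lower, where 3083 of all 24704 genes were higher and 3209 lower; these shares were not tested against each other.

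Protein-coding genes also differed by length. Fold changes correlated with gene length at a Spearman rho of −0.32 across 19686 genes, which are not independent replicates. In the shortest of 5 bins (median 1.96 kb), 14.6% of genes were higher and 2.26% lower. In the longest (median 113.2 kb), 5.41% were higher and 31.5% lower. The median log2 fold change went from 0.17 in the shortest bin to −0.33 in the longest.

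**Figure D2:**
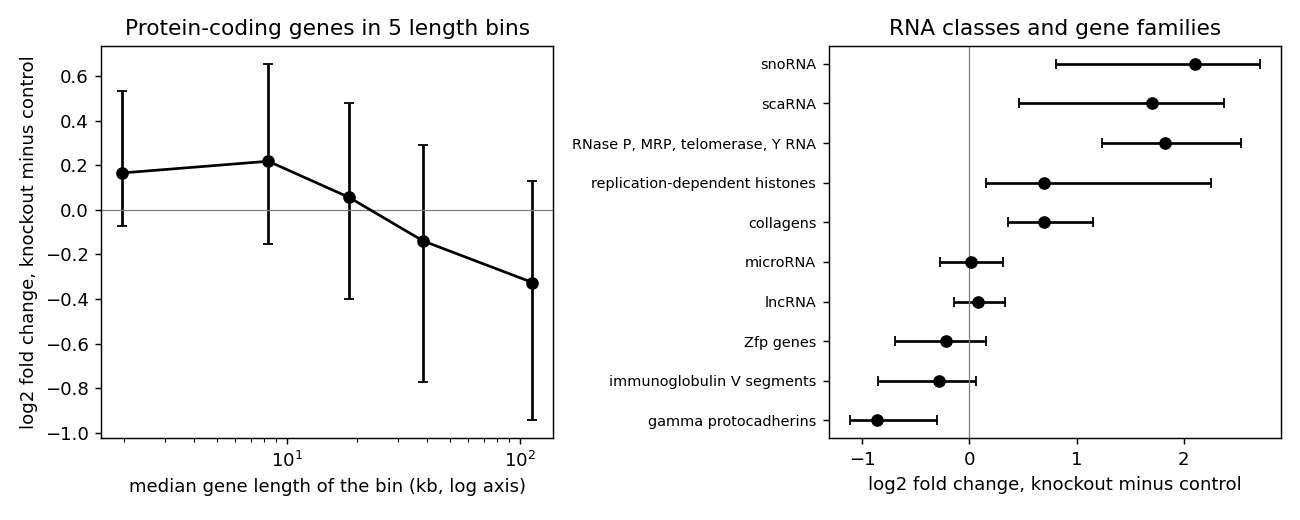
Left, median log2 fold change (knockout minus control) of protein-coding genes in 5 bins of gene length, on a log axis of kb; right, medians for RNA classes and gene families; lines span the middle quartiles. The longest genes have a median of −0.33 and the snoRNAs one of 2.10.

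Some cell cycle genes were lower in the knockout: past the threshold, 11 of 27 fell and 0 rose (12 fell when adjusted over the list alone). The list had a mean log2 fold change of −0.64 and camera's adjusted p = 0.010. With the correlation estimated (0.15, against the preset 0.01) camera's adjusted p = 0.81, so the list's call was lost. It was also lost with fry (0.054), among genes above the median level (0.089) and with the snoRNA covariate. Top2a, which untangles replicated DNA, stood at −1.90 ± 0.27, the proliferation marker Mki67 at −1.71 ± 0.32, the spindle motor Kif11 at −1.69 ± 0.23 and the cyclin Ccnb2 at −1.20 ± 0.20. The other 16 measured members did not pass and lay on both sides of 0. Named after their values were seen, they ran from Bub1 at −0.97 to Mcm5 at 0.62, with Pcna at −0.0017.

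Immediate early genes, which respond within minutes to stimulation or handling, were higher: 5 of 15 rose and 0 fell (6 rose when adjusted over the list alone), with a mean of 0.61 and an adjusted p = 0.023. With an estimated correlation the adjusted p = 0.81. Junb rose by 2.17 ± 0.22, Egr1 by 0.95 ± 0.23, Ccn1 by 0.86 ± 0.22 and Ccn2 by 0.76 ± 0.19. The call did not hold without control replicate 3 (adjusted p = 0.067), without control replicate 1 (0.074), with Xist as a covariate (0.088), with the length trend removed (0.22), with fry (0.065) or with filters at the 25th percentile (0.073) and the median (0.089) of mean level, nor with the snoRNA covariate. Egr1, Ccn1 and Ccn2 lost their own calls without control replicate 3 or with the length trend removed, and Ccn1 and Ccn2 also without control replicate 1. Ccn1 lost its call without knockout replicate 4 as well, and all 3 did with Xist as a covariate.

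Markers of endothelial cells, the cell type targeted, moved in both directions. Of 16 pan-endothelial genes 5 rose and 5 fell (7 and 6 when adjusted over the list alone), and the list did not pass (adjusted p = 0.82). Its mean of −0.06 differed in sign from its median of 0.41 and from camera's direction. Vwf, the clotting factor carrier, rose by 1.61 ± 0.24 and Egfl7 by 1.06 ± 0.19, while the junction gene Cdh5 stood at −1.52 ± 0.26 and the angiopoietin receptor Tek at −2.01 ± 0.36. Named after their values were seen, the other members past the threshold were Cldn5, Eng and Sox18, which rose, and Pecam1, Erg and Emcn, which fell. Without control replicate 3 the calls of Cldn5, Eng, Sox18, Erg and Emcn were lost, and without control replicate 1 those of Cldn5, Eng, Sox18 and Emcn. Emcn also lost its call without control replicate 4 or knockout replicate 3, and Erg and Emcn with the length trend removed. With Xist as a covariate Pecam1 (−1.56, adjusted p = 0.056), Cldn5 (0.78), Eng (0.90), Sox18 (0.93) and Emcn (−1.57) did not pass, at log2 fold changes of the same sign.

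Osmoprotective targets of NFAT5 did not pass as a list (adjusted p = 0.29), with 3 of 8 lower and 0 higher, and also 3 when adjusted over the list alone. The myo-inositol transporter Slc5a3 stood at −2.09 ± 0.20 and the amino acid transporter Slc38a2 at −1.12 ± 0.28. The knockout mean of Slc5a3 (1.71) lay below the arrays' lower quartile of 2.02, so the size of its fall is uncertain. The chaperone Hspa4l stood at −1.09 ± 0.34, and the betaine transporter Slc6a12, which did not pass, at 0.28 ± 0.18. Slc38a2 and Hspa4l lost their calls without control replicate 1 or 3, and Hspa4l also without control replicate 4 or with the length trend removed. Neither passed with Xist as a covariate.

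Extracellular matrix genes rose at 9 of 19 and fell at 1, with a mean of 0.47, and the list missed the threshold (adjusted p = 0.088). It passed with the length trend removed from protein-coding genes (adjusted p = 0.0070) and without knockout replicate 4 (0.030). Col4a2, a basement membrane collagen, rose by 1.62 ± 0.20, elastin (Eln) by 1.47 ± 0.22 and the crosslinking enzyme Loxl1 by 1.45 ± 0.21, while Postn stood at −1.72 ± 0.23. Among all 44 collagen genes, a family examined after the calls were seen, 20 were higher and 0 lower, with a median of 0.70.

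Genes of vascular growth and tone moved both ways, with 4 of 17 higher and 3 lower (adjusted p = 0.91). Tgfb1, a growth factor of vessel wall remodelling, rose by 1.58 ± 0.19 and the prostacyclin synthase Ptgis by 1.03 ± 0.19. Igf1 stood at −1.26 ± 0.24 and Bmpr2, the receptor mutated in heritable pulmonary hypertension, at −1.62 ± 0.32. The list for BMP and Notch signalling, which holds receptors as well as targets, was higher at 5 of 12 and lower at 1 (adjusted p = 0.20). Smad6 stood at 1.33 ± 0.22, Id1 at 1.27 ± 0.20 and Id3 at 1.22 ± 0.24, and the 1 lower member was the receptor Bmpr2, given above. Named after their values were seen, the receptor Acvrl1 also rose, and the Notch targets Hey1, Hey2 and Hes1 did not pass. Of the pericyte list 4 of 10 rose and 3 fell (adjusted p = 0.82), among them Notch3 at 1.69 ± 0.24, Cspg4 at 1.69 ± 0.34, Gucy1b1 at −1.51 ± 0.22 and Gucy1a1 at −1.42 ± 0.29, which did not pass with Xist as a covariate (−1.26, adjusted p = 0.051).

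Genes of the hypoxia-inducible list were higher at 2 of 23 and lower at 6 (adjusted p = 0.49). All arrays were from hypoxia, and preparations with inadequate expression responses to it had been left out. These values therefore do not measure induction by hypoxia. Kdm3a stood at −1.25 ± 0.24, P4ha1 at −1.21 ± 0.29, Bnip3 at −0.98 ± 0.24 and Ddit4 at 0.99 ± 0.24. Without control replicate 3 the calls of P4ha1, Bnip3 and Ddit4 were lost, without control replicate 1 those of P4ha1 and Ddit4, and without control replicate 4 those of P4ha1 and Bnip3. P4ha1 and Ddit4 did not pass with Xist as a covariate. Oxidative phosphorylation genes were higher at 23 of 74 and lower at 3 (adjusted p = 0.11, but 0.017 without knockout replicate 1 and 0.049 without control replicate 4), led by Cox4i1 at 1.57 ± 0.21, Uqcrc1 at 1.60 ± 0.24, Ndufs1 at −1.42 ± 0.23 and Ndufb2 at 1.23 ± 0.20. Cytosolic ribosomal protein genes were higher at 16 of 67 and lower at 6 (adjusted p = 0.11), with Rpl41 at 2.25 ± 0.29, Rps19 at 2.11 ± 0.33, Rps2 at 2.03 ± 0.32 and Rpl4 at −1.18 ± 0.22. Some other members of this list lay below the arrays' lower quartile of 2.02 in both groups, so changes in them may have been missed.

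**Figure D3:**
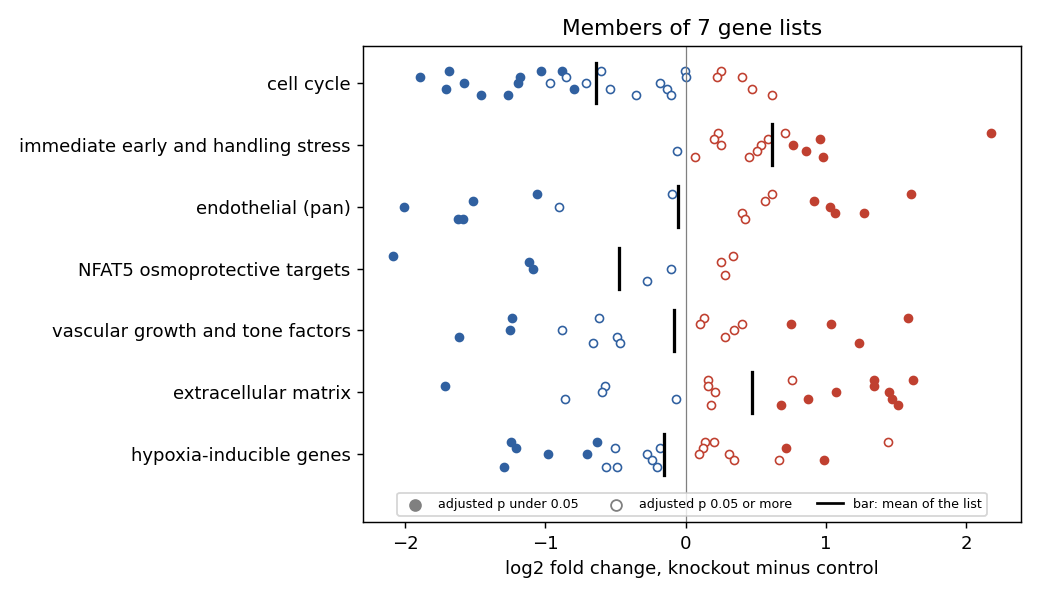
Log2 fold change (knockout minus control) of each measured member of 7 gene lists; filled points have an adjusted p under 0.05, open points do not, and bars mark list means. The cell cycle mean lies at −0.64 and the immediate early mean at 0.61, while the pan-endothelial members lie on both sides of 0.

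Markers of other cells and tissues gave no list past the threshold. Of 11 thymus genes 1 rose and 1 fell (adjusted p = 0.82): Foxn1 at 1.06 ± 0.30 and Psmb11 at −0.76 ± 0.20, the latter with a knockout mean of 1.67, also below 2.02. Preparations with contaminating tissue such as thymus had been left out by the authors, so the arrays were selected on this trait. Alveolar macrophage markers stood at a mean of −0.73, with 1 of 8 lower, Mrc1 at −1.47 ± 0.28, and 5 lower when adjusted over the list alone (adjusted p = 0.11 with camera and 0.015 with fry). Ciliated airway markers were lower at 5 of 10 and higher at 1 (adjusted p = 0.11), with Ccdc39 at −1.92 ± 0.42, Dnah5 at −1.08 ± 0.25, Spag17 at −0.95 ± 0.21 and the ciliary regulator Foxj1 at 1.59 ± 0.18. Alveolar type 2 markers were higher at 2 of 12 and lower at 4 (adjusted p = 0.35), with Fasn at 1.42 ± 0.18, Napsa at 1.09 ± 0.21, Cxcl15 at −1.66 ± 0.21 and Sftpa1 at −1.04 ± 0.20. Without control replicate 3 Foxn1, Psmb11, Ccdc39, Dnah5 and Spag17 lost their calls, and without control replicate 1 Foxn1, Psmb11 and Ccdc39 did. With Xist as a covariate Foxn1, Psmb11, Ccdc39 and Dnah5 did not pass, nor did Spag17 with the length trend removed.

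Sex-linked genes differed between arrays of the same group. Xist was high on control replicate 1 (8.22) and between 2.03 and 2.37 on each other array. The Y-linked Kdm5d stood at 3.94 and 4.02 on control replicates 4 and 3, at 1.57 on control replicate 1 and at 1.96 to 2.16 on the knockouts. Uty stood at 4.48 and 4.90 on control replicates 4 and 3 and at 2.22 on control replicate 1. In the same order, Eif2s3y stood at 4.59, 4.80 and 1.63. By these genes the controls were of mixed sex, while no knockout array had high Xist. Uty reached 4.30 and 3.29 on knockout replicates 4 and 3 and 2.05 on knockout replicate 1, where Eif2s3y stood at 2.66. As Xist was low there too, the sex of knockout replicate 1 could not be told. The groups may thus differ in their balance of sexes.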

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

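Tests of RNA preparation over all genes and of a lower endothelial share were chosen only after the results they bear on were seen, as were the comparison of left-out controls and the ratio of fold changes below. Among the probe sets without a gene name, which the comparisons above did not use, 102 were higher in the knockout than in the controls and 107 lower, with a median log2 fold change of 0.04.

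The first pattern was that 6292 genes differed between the groups, with most snoRNAs, scaRNAs and RNAs of RNase P and related particles higher, and longer genes more often lower. Replication-dependent histone genes were higher at 22 of 45 and lower at 0, while cell cycle genes were lower at 11 of 27 and higher at 0. Of 534 microRNAs 43 were higher and 40 lower, but their median level of 1.81 to 2.05 per array leaves open whether they were measured above background. No RNA class was tested as a set. With the average trend in gene length removed from each array, 75.2% of 5569 protein-coding calls remained in the same direction. When both fits were over protein-coding genes, 73.2% of 5854 remained. The average trend thus did not account for most calls. Median log2 fold changes of the length bins spanned only 0.22 to −0.33, while 3810 calls exceeded 2-fold, so most calls were likely to stay. A steeper trend among brighter genes was not removed and stays open. The 200 genes nearest Nfat5 in length and level had a median of −0.66. Variation in RNA preparation or labelling may be the source and stays open. The median correlation over 6 comparisons of disjoint arrays was 0.0059, below the bound of 0.1 set against that explanation. The values spread from −0.25 to 0.24 (SD 0.19), a spread weighed only after the values were seen. Each within-group pair was ordered by its snoRNA level, which differed by only 0.048 to 0.195 between control arrays and by 0.055 to 0.998 between knockout arrays. Where that difference was small the sign of the correlation was nearly arbitrary, and pairs shared arrays, so the median does not decide. A difference in preparation that followed the groups cannot be told apart from genotype or tamoxifen. Without the control array with high Xist 49.3% of calls stayed, under the bound of 50% set in advance as favouring that explanation; leaving out control replicate 3, which has low Xist, kept 45.3%, and over the calls the median ratio of fold changes without the high-Xist array was 0.97 with 0 sign changes, so the count alone does not decide. The 10 splits of the 6 arrays are too few for a share under 0.05: 1 of 10, the real one, gave 6292 genes and the highest other gave 0.

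The second pattern was that endothelial markers moved in both directions. Removal of the average length trend left 88.5% of the spread of the 16 fold changes (SD 1.06 against 1.20). That average trend thus did not account for most of the spread. It was small beside the SD, with bin medians from 0.22 to −0.33, so the spread was likely to stay. The fold changes correlated with gene length across the markers (Spearman rho −0.54), and the calls went from 5 higher and 5 lower to 5 and 3. A steeper length trend among these markers stays open. A lower share of endothelial cells could account at most for the falls and stays open for them, since the 5 markers that rose past the threshold are part of the pattern and their count is no test of it. RNA preparation or labelling could contribute: across these markers the median correlation between disjoint arrays was 0.030, between the bounds of 0 and 0.3, with values from −0.55 to 0.63. The pairs were ordered by the same snoRNA levels, so this median does not decide either. An effect of the knockout or of tamoxifen on endothelial gene expression stays open and was not tested apart from these.

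The third pattern was the fall of Nfat5 in whole lung. A fall shared by genes of like length and level is argued against, since 1 of the 200 nearest protein-coding genes (0.5%) fell as much, at a median of −0.66 for the 200. The knockout named by the design is a candidate explanation for the remainder, as a hypothesis; the size of the fall, in a tissue where only endothelial cells were targeted, was not tested against the cell share.

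For the lists, 7 of the 10 splits gave as many lists past the threshold as the real split (2), the real one included, and the highest other gave 7; the splits are too few for a share under 0.05.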

How the results depend on the processing

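The alternatives restricted to protein-coding genes, with or without the length trend removed, and the snoRNA covariate were chosen after seeing the data. Nfat5 kept its direction under all settings and its call under all but the snoRNA covariate (−2.97, adjusted p = 0.21), from −2.34 to −2.03 when an array was left out. No call changed sign except 1538 under the snoRNA covariate. Leaving out an array gave 2882 to 6155 genes (1391 to 3037 higher, 1491 to 3122 lower) and 1 to 4 lists. Xist as a covariate gave 2827 genes, 1386 higher and 1441 lower, with 1 list. As Xist was high on control replicate 1 alone, this is no check apart from leaving out that array. The snoRNA covariate gave 0 genes, 0 higher and 0 lower, with 4 lists, none of them the cell cycle or immediate early list; it separates the groups without overlap, which costs the fit its contrast. Filters at the 25th percentile and the median of mean level left 1 and 0 lists, camera with an estimated correlation 0 and fry 1. Elsewhere the cause was not tested. The labels do not say what the replicate numbers mark. Deviations from the group means correlated at 0.062, −0.013 and 0.0038 between arrays of the same number, which cannot show whether animals were paired. With the replicate block 6082 genes passed. Of 97 named genes past the threshold, 25 lost their call without control replicate 3, 18 without control replicate 1 and 24 with the Xist covariate, with 0 changes of sign. The filters on mean level gave 6450 and 5788 genes; without detection calls, signal over background was not tested further.

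Some lists that did not pass with all arrays and no covariate changed sign in their mean. Above the 25th percentile of level thymus stood at 0.0084, and above the median thymus stood at 0.24, inflammatory cytokines at 0.085, monocytes at 0.049, T and NK cells at 0.046 and NRF2 targets at −0.031. Renewed quantile scaling gave aerocytes −0.00092, and array weights gave aerocytes −0.00084 and the proteasome 0.0025. Xist as a covariate gave aerocytes −0.021, arterial endothelium −0.021, thymus 0.11 and NRF2 targets −0.037. Removing the length trend gave aerocytes −0.11, vascular factors 0.0042 and the unfolded protein response −0.14. Leaving out an array gave ranges of −0.12 to 0.039 for pan-endothelial genes, −0.030 to 0.031 for aerocytes, −0.078 to 0.088 for arterial endothelium, −0.15 to 0.14 for the proteasome, −0.15 to 0.13 for monocytes, −0.15 to 0.094 for thymus, −0.20 to 0.030 for T and NK cells, −0.0054 to 0.69 for erythroid genes and −0.043 to 0.11 for NRF2 targets. Eif2s3y ranged from −1.34 to 0.25.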

Other observations

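Circadian clock genes, a list written before the data were examined, were higher at 6 of 15 and lower at 2, and did not pass as a list (adjusted p = 0.36). The output gene Dbp rose by 1.96 ± 0.28, the repressor Nr1d1 by 1.79 ± 0.21 and Per1 by 1.51 ± 0.27, while the activator Clock stood at −2.20 ± 0.22 (SE, n = 3 per group). The time of day at which lungs were taken is not given in the sources used here. Class II antigen presentation genes were higher at 3 of 7 and lower at 0 (adjusted p = 0.20), with H2-DMa at 0.92 ± 0.21, H2-Eb1 at 0.89 ± 0.21, H2-DMb1 at 0.86 ± 0.18 and H2-Aa, which did not pass, at −0.68 ± 0.22. Glycolysis genes were higher at 3 of 10 and lower at 2 (adjusted p = 0.28), with Pfkl at 1.32 ± 0.20, Hk1 at 0.89 ± 0.19, Pkm at 0.82 ± 0.23 and Pfkp at −0.83 ± 0.26. Gapdh and Pgam1, named after their values were seen, did not pass and lay below the lower quartile of 2.02 in both groups. Without control replicate 3 the 3 class II calls and those of Hk1, Pkm and Pfkp were lost. Without control replicate 1 H2-DMa, H2-Eb1, Pkm and Pfkp lost theirs, Pkm and Pfkp also did without knockout replicate 4, and Pfkp without control replicate 4 or knockout replicate 1. With Xist as a covariate H2-DMa, H2-Eb1, Pkm and Pfkp did not pass, and Pfkp did not with array weights or with the length trend removed.

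The airway protein Bpifa1 stood at −2.11 ± 0.35 and Reg3g at −1.76 ± 0.51, both from the secretory airway list, in which 2 of 8 were lower and 0 higher (adjusted p = 0.20). Lcn2, of the neutrophil list (1 higher and 1 lower of 13, adjusted p = 0.76), stood at −2.04 ± 0.21, and Igkc, of the B and plasma cell list (1 and 1 of 12, adjusted p = 0.22), at −1.96 ± 0.31. Ucp1 and Pck1 of the adipose list stood at −2.33 ± 0.39 and −1.09 ± 0.22, with 2 of 8 lower and 0 higher (adjusted p = 0.27). Reg3g lost its call without control replicate 1, 3 or 4 or knockout replicate 3, and Reg3g and Pck1 did not pass with Xist as a covariate.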
